A study of Mus musculus with 12 samples.

How the data were processed

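Messenger RNA from the left ventricle of 12 mice was sequenced. Per the labels, RNA was selected with oligo(dT) beads, fragmented, reverse transcribed from random hexamers and sequenced as single-stranded DNA circles on a DNA nanoball platform. Samples were grouped by surgery and drug as their labels give them: Sham+control, Sham+pimobendan, TAC+control and TAC+pimobendan, with 3 biological replicates in each, every one a separate mouse. Replicate numbers were treated as names, with no pairing across groups. The authors deposited a single table with an FPKM value (fragments normalised to gene length and to the mapped fragments of the library) and a TPM value for each gene and sample, both rounded to 2 decimals. Within a library the deposited TPM was a constant multiple of the FPKM, between 1.55 and 1.69. The submitters' processing notes name HISAT2 2.0.4, Bowtie2 2.2.5, RSEM 1.2.12, DESeq2 1.4.5 and the build GRCm38, without stating a role or an order for any of them. The table holds no counts, so the depth of each library is unknown and no counting interval or detection floor is given, and a value of 0 may be a failed estimate. Per library, between 1916 and 2328 of the 17052 genes were listed at 0.

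FPKM values were analysed as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (limma-trend: a linear model with 1 mean per group, and variances moderated along mean expression). Genes with at least 1 FPKM in at least 3 samples were tested, which kept 11415. All 12 libraries entered a single fit with 8 residual degrees of freedom. The comparisons were TAC+control minus Sham+control, TAC+pimobendan minus TAC+control, Sham+pimobendan minus Sham+control, TAC+pimobendan minus Sham+pimobendan, the interaction (the difference between both TAC effects) and the mean of both TAC effects. P values were adjusted by Benjamini-Hochberg over all genes tested, and a gene was called at an adjusted p under 0.05. Fold changes are on the log2 scale of FPKM + 1 with the standard error of limma, and group values are means of FPKM with the standard deviation. The design, the comparisons, the gene lists, the rule for naming genes and the first set of alternatives were fixed before the data were examined. The plan had a count model for count data and this limma model for FPKM, and only the limma model was applicable.

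Gene lists covered 27 programmes and cell types with at least 5 measured members. The programmes were fetal and hypertrophy genes, sarcomere, calcium handling, potassium and pacemaker channels, matrix and fibrosis, MAP kinase cascade, MAP kinase feedback, immediate early genes, cAMP, adrenergic and phosphodiesterase genes, fatty acid oxidation, glycolysis, TCA cycle and pyruvate, oxidative phosphorylation, interferon response, inflammation, heat shock, ER stress and ATF4, cell cycle, circadian, and glucocorticoid and fasting genes. Cell types were atrial muscle, endothelial, erythroid, fibroblast, macrophage, Schwann, and smooth muscle and pericyte. Lists of markers with under 5 measured members were not tested: adipocyte (2), mesothelial (2), neutrophil (2), skeletal muscle (3), thymus (1) and 0 each for B cells, T and NK cells, and lung. Each list was tested against all other genes with camera from limma at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 27 lists, and again with the correlation estimated from the data. The rotation test fry was run beside it; it asks whether a list's genes move on balance one way and compares the list with no other genes. Calls within a list are given over all genes tested and adjusted over the list alone.

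Genes named were chosen per comparison by a fixed rule. They were 12 panel genes (Nppa, Nppb, Myh7, Myh6, Acta1, Ankrd1, Col1a1, Col3a1, Postn, Ctgf, Atp2a2 and Pde3a), the 5 largest rises and the 5 largest falls among called genes with at least 5 FPKM in the higher group and no overlap between the groups, and the 2 members with the smallest p of each list with a camera call or a called member (3 where a list had 8 or more called members). In the drug comparisons the members of the MAP kinase cascade and of the cAMP list with the smallest p were also named. Gene coordinates, transcript length and GC content came from annotation of GRCm38, matched by NCBI Gene ID; 16941 of 17052 genes matched, and GC content and length were available for 11311 of the 11415 tested. A library's GC trend is Spearman's rho across genes between GC content and the library's deviation from the mean of all libraries. List scores per library are means over members of the log2 difference from the mean of Sham+control, and exact two-sided permutation tests were used for them.

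Alternatives fixed in advance were median-ratio scaling of FPKM, no filter on low values, a mean of at least 1 FPKM, the replicate number as a block, a pseudocount of 0.1 with no filter, an absolute log2 fold change of at least 1, a fit of only the groups compared, the estimated correlation, and leaving out each library in turn. Chosen after seeing the data were TPM in place of FPKM, quantile normalization, removal of each library's trend with GC content and transcript length (loess, span 0.3), array quality weights, a pseudocount of 0.1 with the filter kept, and leaving out TAC+pimobendan replicates 2 and 3. The fit was also tested on simulated data, in which sets of genes were shifted by log2 0.5, 1 or 2. It recovered 38.8%, 95.5% and 98.5% of them for TAC without drug, and 11 genes that were not shifted were called as well. The simulated noise was drawn independently for each gene with its moderated variance. It holds no trend shared by the genes of a library, so these shares may be too high for the real libraries. Other splits of the samples into groups of the same sizes were refitted to see how many calls they gave (10 per comparison of 3 with 3 libraries, 100 drawn with a fixed seed otherwise).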

Results

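Messenger RNA of the left ventricle was sequenced from 12 C57BL/6 mice, 3 in each of 4 groups, and each library came from a separate mouse. The mice had either sham surgery or transverse aortic constriction (TAC), a clip on the aortic arch that loads the left ventricle with pressure, at 8 weeks of age and were sampled at 12 weeks. Within each surgery, mice received pimobendan, a calcium sensitizer and phosphodiesterase inhibitor given for heart failure, at 1 mg/kg/day for 4 weeks, or served as controls without it. The groups are named Sham+control, Sham+pimobendan, TAC+control and TAC+pimobendan. The series asked whether pimobendan limits the hypertrophy caused by pressure overload and whether MAP kinases take part. The deposited table gives FPKM and TPM for 17052 genes and no counts, so the sequencing depth of the libraries is unknown. FPKM summed to between 593203 and 643478 per library, between 10809 and 11292 genes per library reached 1 FPKM, and 11415 genes were tested. Across genes, which are not independent replicates, Pearson's r was between 0.986 and 0.994 for pairs of libraries within a group and between 0.974 and 0.994 for pairs from different groups. On average, TAC+pimobendan libraries held more of the transcripts of low GC content. Spearman's rho across genes between GC content and a library's deviation from the mean of all 12 was -0.21, -0.522 and -0.541 there and between -0.36 and 0.545 in the other 9 libraries (mean difference by a two-sided exact permutation test, p = 0.00909 over 220 splits). This test was not planned, so its p is not that of a contrast fixed in advance. Sham+control replicate 1, at -0.36, lay below TAC+pimobendan replicate 1.

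TAC+control was compared with Sham+control to ask how the left ventricle responds to pressure overload without the drug. Genes of the fetal programme of the loaded heart varied between mice of the same group, in sham groups as well, and none passed the test. The SD of the hypertrophy list score was 0.106 in Sham+control, 0.245 in Sham+pimobendan, 0.133 in TAC+control and 0.067 in TAC+pimobendan. Over the 27 lists the SD in Sham+control ran from 0.011 to 1.00, so the hypertrophy score lay within the range of other lists. Acta1, the skeletal muscle alpha-actin re-expressed in hypertrophy (NCBI Gene 11459; GRCm38 chromosome 8, 123890942 to 123894775), had 230.1 ± 81.2 FPKM (SD, n = 3) in Sham+control and 802 ± 736 in TAC+control, where the individual mice had 1608, 632 and 166. Its log2 fold change was 1.32 ± 0.60 (SE; 95% confidence interval 0.026 to 2.61; limma adjusted p = 0.593). Nppb, which encodes brain natriuretic peptide (NCBI Gene 18158; chromosome 4, 147985086 to 147987205), had 599.6 ± 56.5 FPKM in Sham+control and 776 ± 391 in TAC+control (log2 fold change 0.25 ± 0.35, limma adjusted p = 0.856). Nppa, which encodes atrial natriuretic peptide, had a log2 fold change of -0.52 ± 0.34, and Myh7, the slow myosin heavy chain of the fetal mouse heart, had 0.30 ± 0.92. The adult myosin Myh6, the calcium pump Atp2a2 and the stretch-responsive Ankrd1 had log2 fold changes of 0.011, 0.040 and -0.12. Among matrix genes, Col1a1, Col3a1, Postn and Ctgf stood at -0.25, -0.55, -0.39 and -0.89, and Pde3a, a target of pimobendan, at -0.11.

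**Figure D1:**
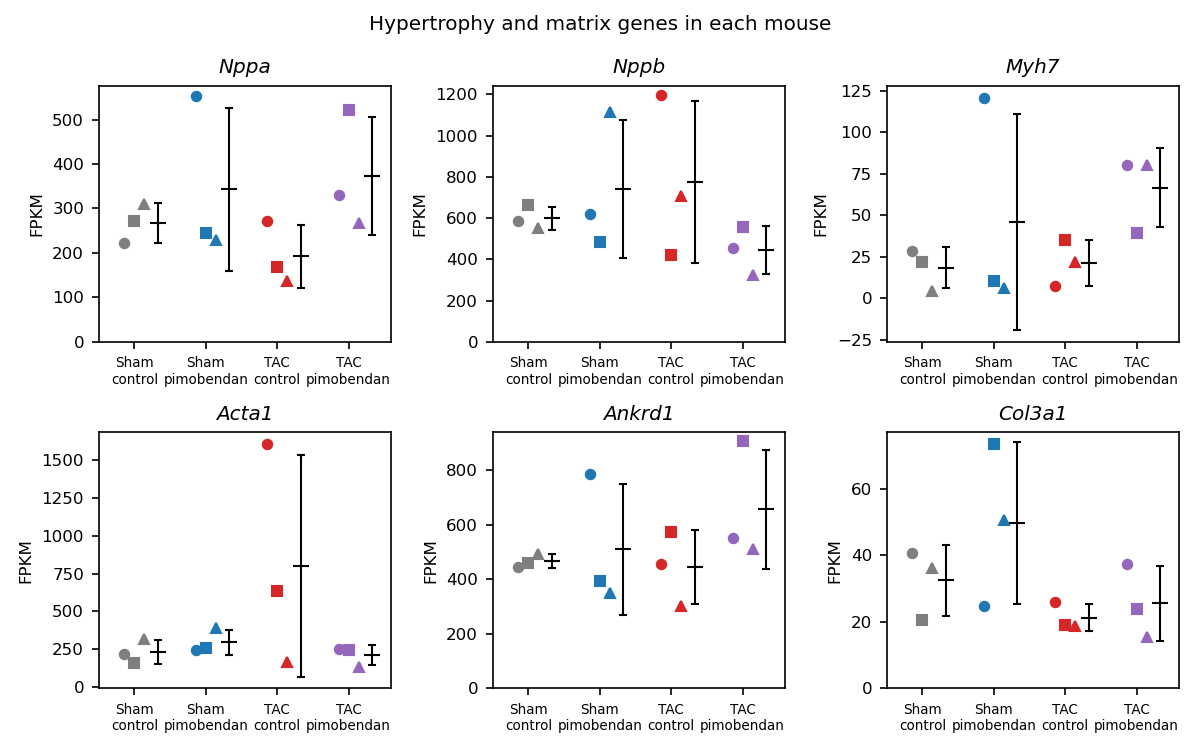
FPKM of Nppa, Nppb, Myh7, Acta1, Ankrd1 and Col3a1 in each of the 12 mice by group; circles, squares and triangles are replicates 1, 2 and 3, and the bars beside them are the mean ± SD (n = 3). A single TAC+control mouse had 1608 FPKM of Acta1, and the values of Acta1 in the other TAC+control mice were 632 and 166.

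Of the 27 gene lists fixed in advance, camera with a preset correlation placed 8 higher and 8 lower than other genes in TAC+control, and none held with an estimated correlation. The rotation test fry called 0 lists as moving one way in each of the 5 comparisons; its smallest adjusted p was 0.325 for TAC without drug, 0.0633 for pimobendan after TAC, 0.91 for pimobendan after sham, 0.301 for TAC under pimobendan and 0.223 for the interaction. Regardless of direction it called 0, 12, 0, 10 and 4 lists in the same order. All 7 measured erythroid markers had positive log2 fold changes (median 1.03, camera adjusted p = 4.68e-10; adjusted p = 0.262 with an estimated correlation). Of these 6 passed limma when adjusted over the list alone and 0 over all genes. Alas2, the first enzyme of heme synthesis in red cells, had 5.39 ± 1.23 FPKM in Sham+control and 11.9 ± 1.73 in TAC+control, and Bpgm had a log2 fold change of 0.40 ± 0.13. All 23 interferon-response genes had negative log2 fold changes (median -0.34, camera adjusted p = 0.000276; adjusted p = 0.458 with an estimated correlation). Of these 1 passed limma adjusted over the list alone and 0 over all genes. Usp18 stood at -1.33 ± 0.32 and Rsad2 at -0.51 ± 0.15. The heat shock list had a median of 0.080 (camera adjusted p = 0.000276; adjusted p = 0.298 with an estimated correlation). Of its 12 members 2 passed limma adjusted over the list alone and 0 over all genes. Those 2 were the inducible HSP70 chaperones Hspa1b (2.74 ± 0.73) and Hspa1a (2.48 ± 0.71). Hspa1b had 2.93, 49.4 and 52.3 FPKM in the TAC+control mice. Immediate early genes (22 of 24 negative, median -0.80, camera adjusted p = 0.000835; adjusted p = 0.568 with an estimated correlation) included Zfp36 at -1.46 ± 0.38 and Klf6 at -0.82 ± 0.22. MAP kinase feedback genes (12 of 13 negative, median -0.33, camera adjusted p = 0.00328; adjusted p = 0.458 with an estimated correlation) included the ERK phosphatase Dusp6 at -0.67 ± 0.18 and Etv5 at -0.50 ± 0.17. In both of these lists 3 members passed limma adjusted over the list alone and 0 over all genes. Immediate early scores of replicates 1, 2 and 3 were 0.51, 0.64 and -1.16 in Sham+control and -1.28, -1.57 and 0.40 in TAC+control, where replicate 3 of each group stood apart; feedback scores were 0.24, 0.037 and -0.28 in Sham+control and -0.30, -0.86 and -0.071 in TAC+control. Inflammation genes (median -0.29, camera adjusted p = 0.016; adjusted p = 0.458 with an estimated correlation) included the NF-kappaB inhibitor Nfkbia at -0.64 ± 0.15 and the chemokine Ccl5 at -0.58 ± 0.19.

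Camera also called lists of metabolism and muscle genes without drug. Glycolysis genes had a median log2 fold change of 0.091 (camera adjusted p = 0.000276, and adjusted p = 0.458 with an estimated correlation). The TAC+control scores of 0.047, 0.10 and 0.067 lay within the range of Sham+control, which had -0.14, 0.023 and 0.12. Pgam1 stood at 0.58 ± 0.17 and Pfkfb2 at -0.44 ± 0.15. Fatty acid oxidation genes had a median of 0.029 (camera adjusted p = 0.0011, and adjusted p = 0.53 with an estimated correlation). Their scores were 0.10, 0.098 and -0.20 in Sham+control and 0.044, 0.055 and 0.077 in TAC+control. Every TAC+control library thus lay below Sham+control replicates 1 and 2, and the direction rested on Sham+control replicate 3. Cpt1b stood at 0.17 and Fabp3 at 0.17. The medians were 0.037 for the TCA cycle (camera adjusted p = 0.00221; adjusted p = 0.161 with an estimated correlation) and 0.029 for oxidative phosphorylation (camera adjusted p = 0.0056; adjusted p = 0.568 with an estimated correlation). The medians of the fatty acid, TCA cycle, oxidative phosphorylation and sarcomere lists were negative on TPM and under quantile normalization, where camera placed oxidative phosphorylation lower (camera adjusted p = 0.0101). Under that normalization it called none of the fatty acid, glycolysis, TCA cycle, hypertrophy and sarcomere lists. Pdhb stood at 0.17, Ogdh at 0.14, Ndufs7 at 0.12 and Ndufa1 at -0.14. Hypertrophy genes had a median of 0.088 (camera adjusted p = 0.0245; adjusted p = 0.386 with an estimated correlation). The smallest p in it belonged to Acta1 and Xirp1 (0.49 ± 0.28). Sarcomere genes had a median of 0.024 (camera adjusted p = 0.0102; adjusted p = 0.298 with an estimated correlation). Actc1 stood at 0.34 ± 0.13 and Actn2 at 0.14. Placed lower were cell cycle genes (-0.43, camera adjusted p = 0.0241; adjusted p = 0.642 with an estimated correlation), including Mcm3 and Cdc20 at -0.46 and -0.65. ER stress genes were placed lower as well (-0.29, camera adjusted p = 0.0327; adjusted p = 0.442 with an estimated correlation), including Chac1 and Dnajb9 at -1.33 and -0.46. Endothelial markers had a median of -0.19 (camera adjusted p = 0.0223; adjusted p = 0.458 with an estimated correlation). Esam stood at -0.39 and Sox17 at -0.63. Smooth muscle and pericyte markers had -0.18 (camera adjusted p = 0.0223; adjusted p = 0.458 with an estimated correlation). Myh11 stood at -0.53 and Cnn1 at -0.55. In this comparison limma called 0 of 11415 genes at an adjusted p under 0.05 (951 at an unadjusted p under 0.05, where chance gives 570.75; smallest adjusted p = 0.205). Without TAC+control replicate 1, 4 genes passed (Hspa1b, Hspa1a, Depp1 and Zfp799), without Sham+control replicate 1 only Cited2 did, and with only these groups fitted G0s2 and Lgals3bp did, of which those outside the naming rule were chosen after their values were seen. The number of lists past camera was 9 without Sham+control replicate 1 and 8 without TAC+control replicate 2.

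TAC+pimobendan was compared with TAC+control to ask what the drug changes in the loaded ventricle. With pimobendan 360 genes rose and 13 fell, and the genes that rose included 9 of 23 interferon-response genes and the muscle genes Pln and Xirp2. The genes that rose had a median GC content of 43.4%, against 50.5% for all genes tested, and the TAC+pimobendan libraries shared the trend towards low GC content. The mean rho of the libraries with GC content was -0.42 in TAC+pimobendan and 0.15 in TAC+control. The two-sided exact permutation p between these groups was 0.1, the smallest that 20 splits allow. Srsf5, a splicing factor (NCBI Gene 20384; chromosome 12, 80945504 to 80961528), rose from 31.1 ± 1.5 to 78.0 ± 14.2 FPKM (SD, n = 3; log2 fold change 1.28 ± 0.16 (SE), limma adjusted p = 0.0309). Its values were also higher with the drug after sham, where no gene passed. They were 51.4, 42.1 and 54.4 FPKM in Sham+control and 89.4, 91.4 and 61.8 in Sham+pimobendan. Iigp1, an interferon-inducible GTPase (NCBI Gene 60440; chromosome 18, 60373621 to 60392634), rose from 6.86 ± 1.46 to 37.7 ± 35.1 FPKM, with 12.3, 23.1 and 77.8 FPKM in the TAC+pimobendan mice (log2 fold change 1.92 ± 0.45, limma adjusted p = 0.0457). The other large rises were Fbxo32, the muscle ubiquitin ligase atrogin (1.21 ± 0.27), Lgals3bp (1.17 ± 0.21) and Irf7, a transcription factor of the interferon response (1.12 ± 0.24). The largest falls were in Alas2 (11.9 ± 1.73 to 4.72 ± 1.73 FPKM, log2 fold change -1.22 ± 0.26), the phosphatase Alpl (-0.65 ± 0.11), the copper chaperone Sco2 (-0.56 ± 0.12), cardiac alpha-actin Actc1 (-0.53 ± 0.13) and the cytochrome oxidase subunit Cox6a1 (-0.46 ± 0.10). For each gene named here as risen or fallen with pimobendan after TAC, the values of the groups did not overlap. The naming rule asked this of the largest rises and falls, so it adds no support for them, and chance gives it for 10% of genes. TAC+control values of many risen genes were also low: without drug, the same 360 genes had a median log2 fold change of -0.224, and 10 were positive, but TAC+control enters both comparisons with opposite signs.

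Among the gene lists, 9 of 23 interferon-response genes rose over all genes tested and 17 when adjusted over the list alone (median 0.68, camera adjusted p = 3.93e-08; adjusted p = 0.314 with an estimated correlation). They included Rsad2, an antiviral enzyme, at 0.80 ± 0.15, Rtp4 at 0.67 ± 0.12 and Ifit1 at 1.36 ± 0.28. All 15 macrophage markers had positive log2 fold changes (median 0.29, camera adjusted p = 0.0624). The protease Ctss rose by 0.82 ± 0.17 and the mannose receptor Mrc1 stood at 0.75 ± 0.19, and 2 passed when adjusted over the list alone. Of the inflammation genes Ccl5 rose by 0.93 ± 0.19 and Ccl8 stood at 0.64 ± 0.24. In this list 1 of 22 genes passed over all genes and 1 adjusted over the list alone. Phospholamban (Pln), the brake on the calcium pump, rose from 2427 ± 172 to 3446 ± 404 FPKM. It was 1 of 15 calcium-handling genes past limma over all genes, and 5 passed adjusted over the list alone. Trdn stood at 1.05 ± 0.27. In the sarcomere list, Nebl rose by 0.81 ± 0.20 while Actn2 fell (-0.38 ± 0.078). Camera placed the list lower (median -0.087 against a mean of 0.020, camera adjusted p = 0.00387; adjusted p = 0.252 with an estimated correlation). Of the hypertrophy list Xirp2 rose (0.98 ± 0.23) and Flnc stood at -0.41 ± 0.11. Other risen list members were the potassium channel subunit Kcnv2 (0.66 ± 0.14), lipoprotein lipase Lpl (0.73 ± 0.17), thymidylate synthase Tyms (0.55 ± 0.13), the anchoring protein Akap6 (0.50 ± 0.12) and the phosphodiesterase Pde1c (0.79 ± 0.19).

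Erythroid markers were lower with the drug after TAC in all 7 members (median -1.27, camera adjusted p = 1.23e-06; adjusted p = 0.314 with an estimated correlation). Alas2 passed over all genes, and 5 members passed adjusted over the list alone. Hba-a1 had 1805 ± 490.4 FPKM in TAC+control and 607 ± 189 in TAC+pimobendan (limma adjusted p = 0.0536). Camera also placed lower oxidative phosphorylation (31 of 37 negative, median -0.12, camera adjusted p = 1.36e-08; adjusted p = 0.314 with an estimated correlation). Ndufs7 and Sdhb stood at -0.33 and -0.28. The same held for glycolysis (median -0.15, camera adjusted p = 5.65e-06; adjusted p = 0.314 with an estimated correlation). Pkm and Gpi1 stood at -0.35 and -0.26. Heat shock genes were also placed lower (median -0.25, camera adjusted p = 1.85e-05; adjusted p = 0.252 with an estimated correlation). Hspb1 and Hspa8 stood at -0.71 and -0.44. Fatty acid oxidation genes stood lower (median -0.11 against a mean of -0.040, camera adjusted p = 0.00172, and adjusted p = 0.808 with an estimated correlation). The scores of this list were 0.044, 0.055 and 0.077 in TAC+control and 0.0077, -0.13 and 0.18 in TAC+pimobendan. Acadvl stood at -0.25. TCA cycle genes stood lower too (median -0.083, camera adjusted p = 0.00365; adjusted p = 0.199 with an estimated correlation). Suclg1 and Dlst stood at -0.23 and -0.25. Under quantile normalization camera called none of the oxidative phosphorylation, fatty acid, glycolysis, TCA cycle and sarcomere lists, and the medians of the TCA cycle and sarcomere lists were positive. Hypertrophy markers of the panel did not pass: Acta1 had 209 ± 68.1 FPKM in TAC+pimobendan (log2 fold change -1.46 ± 0.60, limma adjusted p = 0.144), and Nppb (-0.71 ± 0.35), Nppa (0.96 ± 0.34), Myh7 (1.76 ± 0.92) and Ankrd1 (0.56 ± 0.30) had limma adjusted p of 0.21, 0.10, 0.24 and 0.25. Col1a1, Col3a1, Postn, Ctgf, Atp2a2, Myh6 and Pde3a stood at -0.0050, 0.18, 0.65, 0.35, -0.011, -0.064 and 0.36.

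Limma called 373 of 11415 genes in this comparison (3040 at an unadjusted p under 0.05; smallest adjusted p = 0.0309), and 22 of the calls had an absolute log2 fold change of at least 1. The genes that rose had a median transcript length of 4798 bases, against 3107 for all genes tested, and Spearman's rho across genes between GC content and log2 fold change was -0.50. The number of calls was 0 after removal of each library's GC and length trend, 0 under quantile normalization, with no filter on low values, with only these groups fitted or with TAC+pimobendan replicates 2 and 3 left out, 1 (Srsf5) under median-ratio scaling or with a replicate block, 2 (Srsf5 and Evi2) with a pseudocount of 0.1 and no filter, 1170 on TPM and 1315 with array weights. Leaving out 1 library gave 0 calls without TAC+pimobendan replicate 2 or TAC+control replicate 3, 3 without TAC+pimobendan replicate 3 (G0s2, Srsf5 and Myh7b) or TAC+control replicate 1 (Hspa1b, Hspa1a and Zfp799, all 3 lower and none among the 373), and 1187 without TAC+pimobendan replicate 1. Of these genes, those outside the naming rule were chosen after their values were seen.

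**Figure D2:**
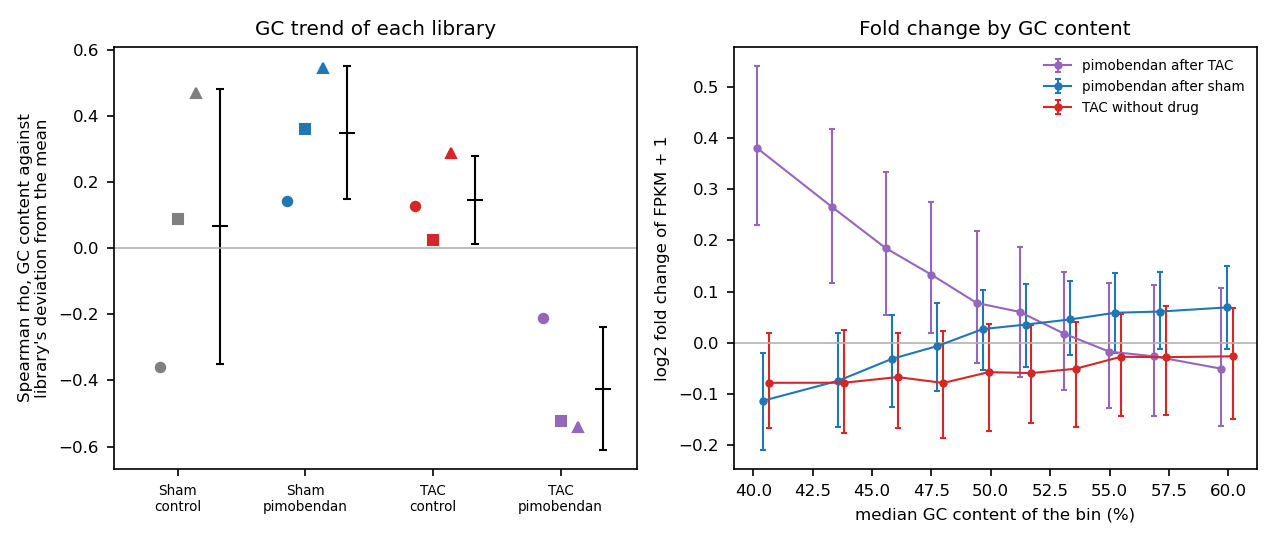
Left, Spearman's rho across genes between GC content and each library's deviation from the mean of all libraries, with circles, squares and triangles for replicates 1, 2 and 3 and bars for mean ± SD (n = 3). Right, median log2 fold change of FPKM + 1 in bins of genes ordered by GC content (%), with bars for the lower and upper quartile, in which genes of low GC content stood higher with pimobendan after TAC.

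MAP kinase genes were examined because the study names these kinases as a route of the drug's action; the table holds their transcripts and not their phosphorylation. With pimobendan after TAC, 1 of 42 cascade genes rose over all genes and 0 adjusted over the list alone (median log2 fold change 0.089, camera adjusted p = 0.974). This was Rps6ka3, a ribosomal S6 kinase downstream of ERK, with 3.29 ± 0.158 FPKM in TAC+control and 6.05 ± 1.24 in TAC+pimobendan (log2 fold change 0.70 ± 0.17, limma adjusted p = 0.0482). Map2k2, which encodes the ERK kinase MEK2, stood at -0.31 ± 0.10 (limma adjusted p = 0.0708). In the cascade 11 of 42 genes had an unadjusted p under 0.05, against 3040 of all 11415 genes tested. Regardless of direction, fry called the cascade (fry adjusted p = 0.0054) and the MAP kinase feedback list (fry adjusted p = 0.0146), among the 12 lists it called in this comparison. Of 13 MAP kinase feedback genes, Etv5, a transcription factor induced by ERK signalling, rose from 3.88 ± 0.627 to 7.64 ± 0.496 FPKM. Etv5 had 6.57, 6.78 and 4.48 FPKM in Sham+control and 7.63, 6 and 4.83 in Sham+pimobendan. Every TAC+control value lay below these, so low TAC+control values were part of the difference. Of the list 2 higher and 1 lower passed adjusted over the list alone, and Spred1 stood at 0.44 ± 0.12 (camera adjusted p of the list = 0.706). The 24 immediate early genes had a median of -0.0081 with 12 positive and 12 negative (camera adjusted p = 0.326). After sham surgery 0 of 42 cascade genes passed limma with pimobendan, over all genes and adjusted over the list alone, and 1 had an unadjusted p under 0.05. Those with the smallest p were Rras2 (0.31 ± 0.14) and Sos1 (-0.25 ± 0.12).

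Sham+pimobendan was compared with Sham+control for the effect of the drug without pressure overload. No single gene passed, and camera called the matrix, fatty acid oxidation, erythroid and heat shock lists. Of 10 splits of these libraries, the real one included, 8 gave at least 4 lists, so chance cannot be excluded for this count. Matrix genes stood higher with the drug (23 of 27 positive, median 0.33, camera adjusted p = 0.000157; adjusted p = 0.86 with an estimated correlation), with scores of -0.016, 0.58 and 0.30 in the Sham+pimobendan libraries against the Sham+control mean. Fibroblast markers were positive in 10 of 14 (median 0.15, camera adjusted p = 0.0949). Elastin (Eln) had 6.5 ± 0.62 FPKM in Sham+control and 13.8 ± 2.31 in Sham+pimobendan, and fibrillin 1 (Fbn1) had 5.92 ± 1.63 and 10.9 ± 4.11. Fatty acid oxidation genes stood higher (26 of 29 positive, median 0.11, camera adjusted p = 0.00587, and adjusted p = 0.884 with an estimated correlation). The scores of this list were 0.10, 0.098 and -0.20 in Sham+control and 0.33, 0.065 and 0.042 in Sham+pimobendan. Sham+control replicate 3 stood apart, and Sham+pimobendan replicates 2 and 3 lay below the other Sham+control libraries. Camera did not call this list with the GC and length trend removed. Ucp3 stood at 0.97 ± 0.30 and Mlycd at 0.36 ± 0.12. Erythroid markers stood lower (6 of 7 negative, median -1.08, camera adjusted p = 6.09e-05; adjusted p = 0.672 with an estimated correlation). Alas2 stood at -0.77 ± 0.26 and Hbb-bt at -1.22 ± 0.42. Of these markers 5 passed limma adjusted over the list alone and 0 over all genes. Heat shock genes stood lower in all 12 members (median -0.26, camera adjusted p = 0.000136, and adjusted p = 0.672 with an estimated correlation). The groups overlapped, with scores of 0.14, 0.17 and -0.31 in Sham+control and -0.23, -0.40 and -0.15 in Sham+pimobendan. Hsp90aa1 stood at -0.72 ± 0.23 and Dnaja1 at -0.51 ± 0.21. In the cAMP, adrenergic and phosphodiesterase list Pde2a and the receptor Adra1b had the smallest p (0.40 ± 0.12 and 0.45 ± 0.15). Of the panel, Nppa, Nppb, Myh7, Myh6, Acta1 and Ankrd1 had log2 fold changes of 0.25, 0.21, 0.48, -0.10, 0.38 and 0.033. Col1a1, Col3a1, Postn, Ctgf, Atp2a2 and Pde3a had 0.35, 0.52, -0.26, 0.48, 0.011 and 0.19. Limma called 0 genes (518 at an unadjusted p under 0.05; smallest adjusted p = 0.910), and 4 lists passed camera; Spearman's rho between GC content and log2 fold change was 0.38, and GC content and length accounted for 14.8% of its variance (TAC without drug 3.86%, pimobendan after TAC 28.4%, TAC under pimobendan 43.7%, interaction 36.5%). The number of lists was 10 without Sham+control replicate 1 or Sham+pimobendan replicate 3 and 8 without Sham+pimobendan replicate 1.

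TAC+pimobendan was compared with Sham+pimobendan for the response to pressure overload under the drug. Under pimobendan 530 genes rose after TAC and 28 fell, with Ttn and Trdn of muscle among the rises and Acta2 and Pecam1 of vessels among the falls. The genes that rose had a median GC content of 41.8%, against 50.5% for all genes tested. The receptor Gpr22 (NCBI Gene 73010; chromosome 12, 31706867 to 31713926) rose from 2.67 ± 0.80 to 8.99 ± 2.37 FPKM (SD, n = 3; log2 fold change 1.44 ± 0.21 (SE), limma adjusted p = 0.0314). Further large rises were in Iigp1 (1.76 ± 0.45), Zfp445 (1.4 ± 0.30), triadin Trdn of the calcium release complex (8.77 ± 1.99 to 25.7 ± 10.8 FPKM) and the actin-binding Nexn (1.36 ± 0.25). Smooth muscle actin Acta2 (NCBI Gene 11475; chromosome 19, 34240336 to 34255585) had the largest fall, from 127 ± 51.7 to 36.8 ± 17.0 FPKM (limma adjusted p = 0.0314). The collagen Col5a3 (-1.04 ± 0.27), the transcription factor Cebpd (-0.81 ± 0.17), Nfkbia (-0.72 ± 0.15) and Rnf144a (-0.66 ± 0.17) fell as well. For each gene named here as risen or fallen after TAC under the drug, the values of the groups did not overlap, which the naming rule asked of the largest rises and falls. Among muscle genes Ttn (0.65 ± 0.14), Nebl (1.03 ± 0.20), Xirp2 (1.21 ± 0.23) and Pln (0.52 ± 0.10) rose. Calcium-handling genes stood higher as a list (13 of 15 positive, median 0.13, camera adjusted p = 0.0382; adjusted p = 0.819 with an estimated correlation). Of them 2 passed limma over all genes and 3 adjusted over the list alone, and after removal of the GC and length trend the list's median turned negative and camera did not call it. The channels Kcnj2 (0.58 ± 0.13) and Kcnj3 (0.61 ± 0.14), the chaperone Hsp90aa1 (0.89 ± 0.23), Lpl (0.81 ± 0.17), the clock output gene Hlf (0.71 ± 0.19), Akap6 (0.48 ± 0.12) and Creb1 (0.62 ± 0.16) rose. Mlycd (-0.48 ± 0.12) and the endothelial genes Esam (-0.39 ± 0.10) and Pecam1 (-0.45 ± 0.12) fell. In the MAP kinase cascade 3 of 42 genes rose over all genes and 3 adjusted over the list alone, Rps6ka3 (0.70 ± 0.17) among them.

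Of the lists under the drug, matrix genes stood lower after TAC (24 of 27 negative, median -0.44, camera adjusted p = 0.000109; adjusted p = 0.819 with an estimated correlation). Limma called 0 members over all genes and 0 adjusted over the list alone, and 12 had an unadjusted p under 0.05. Eln stood at -0.89 ± 0.30 and Col5a1 at -0.52 ± 0.18. Matrix scores were 0.12, -0.061 and -0.37 in TAC+pimobendan, -0.016, 0.58 and 0.30 in Sham+pimobendan and 0.12, -0.29 and 0.17 in Sham+control. Sham+pimobendan enters this comparison and pimobendan after sham with opposite signs. A fall after TAC and high values in Sham+pimobendan therefore cannot be told apart for these genes. Interferon-response genes stood higher (20 of 23 positive, median 0.35, camera adjusted p = 0.0119; adjusted p = 0.819 with an estimated correlation). Over all genes 4 rose, Gbp3 among them (1.04 ± 0.25), and 5 adjusted over the list alone. Oxidative phosphorylation stood lower (median -0.14, camera adjusted p = 0.000776; adjusted p = 0.819 with an estimated correlation). Sdhb stood at -0.30 and Cox4i1 at -0.25. So did fatty acid oxidation (median -0.14, camera adjusted p = 0.0268; adjusted p = 0.819 with an estimated correlation) and glycolysis (median -0.11, camera adjusted p = 0.0382; adjusted p = 0.819 with an estimated correlation). Pfkfb2 stood at 0.42 and Tpi1 at -0.18. Cell cycle genes had a median of -0.45 (camera adjusted p = 0.0291, and adjusted p = 0.819 with an estimated correlation). Their scores were -0.50, 0.67 and 0.050 in Sham+pimobendan, where replicate 2 stood apart, and -0.53, 0.12 and -0.54 in TAC+pimobendan. Mcm2 stood at -0.45 and Tyms at 0.43. Immediate early genes had -0.44 (camera adjusted p = 0.0372; adjusted p = 0.913 with an estimated correlation). Jund stood at -0.47 and Myc at -0.59. Genes of glucocorticoid and fasting responses had -0.31 (camera adjusted p = 0.0382; adjusted p = 0.819 with an estimated correlation). Pdk4 stood at -1.69 ± 0.52 and Sgk1 at -0.98 ± 0.40. Erythroid markers had 0.76 (camera adjusted p = 0.0372; adjusted p = 0.819 with an estimated correlation). Hbb-bt stood at 0.94 and Alas2 at 0.58. Camera did not call sarcomere genes (9 of 17 positive, camera adjusted p = 0.89), endothelial markers (8 of 14 negative, camera adjusted p = 0.107) or smooth muscle and pericyte markers (7 of 12 negative, camera adjusted p = 0.263). Under quantile normalization camera called none of the oxidative phosphorylation, fatty acid, glycolysis, immediate early and glucocorticoid lists, and with the GC and length trend removed the last 4 of these and calcium handling were not called. Members named by the rule that did not pass were Vcam1, Rgs5, Per3, Hspd1 and Enah at 0.51, 0.50, 1.08, 0.34 and 0.25. Of the panel, Nppa, Nppb, Myh7, Myh6, Acta1 and Ankrd1 stood at 0.19, -0.68, 1.58, 0.048, -0.52 and 0.41. Col1a1, Col3a1, Postn, Ctgf, Atp2a2 and Pde3a stood at -0.61, -0.89, 0.53, -1.02, 0.018 and 0.054, none past limma.

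Limma called 558 genes for TAC under pimobendan (2610 at an unadjusted p under 0.05; smallest adjusted p = 0.0314), 51 of them with an absolute log2 fold change of at least 1. Across genes, Spearman's rho between GC content and log2 fold change was -0.64. The number of calls was 0 after removal of the GC and length trend, with no filter on low values, with a replicate block, with a pseudocount of 0.1 and no filter, with only these groups fitted or with TAC+pimobendan replicates 2 and 3 left out, 298 under quantile normalization and 1350 with array weights. It was 328 without Sham+pimobendan replicate 1, 0 without replicate 2 or 3 of Sham+pimobendan or of TAC+pimobendan, and 1222 without TAC+pimobendan replicate 1, and the 10 lists past camera became 4, 5 and 6 without TAC+pimobendan replicates 1, 2 and 3.

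**Figure D3:**
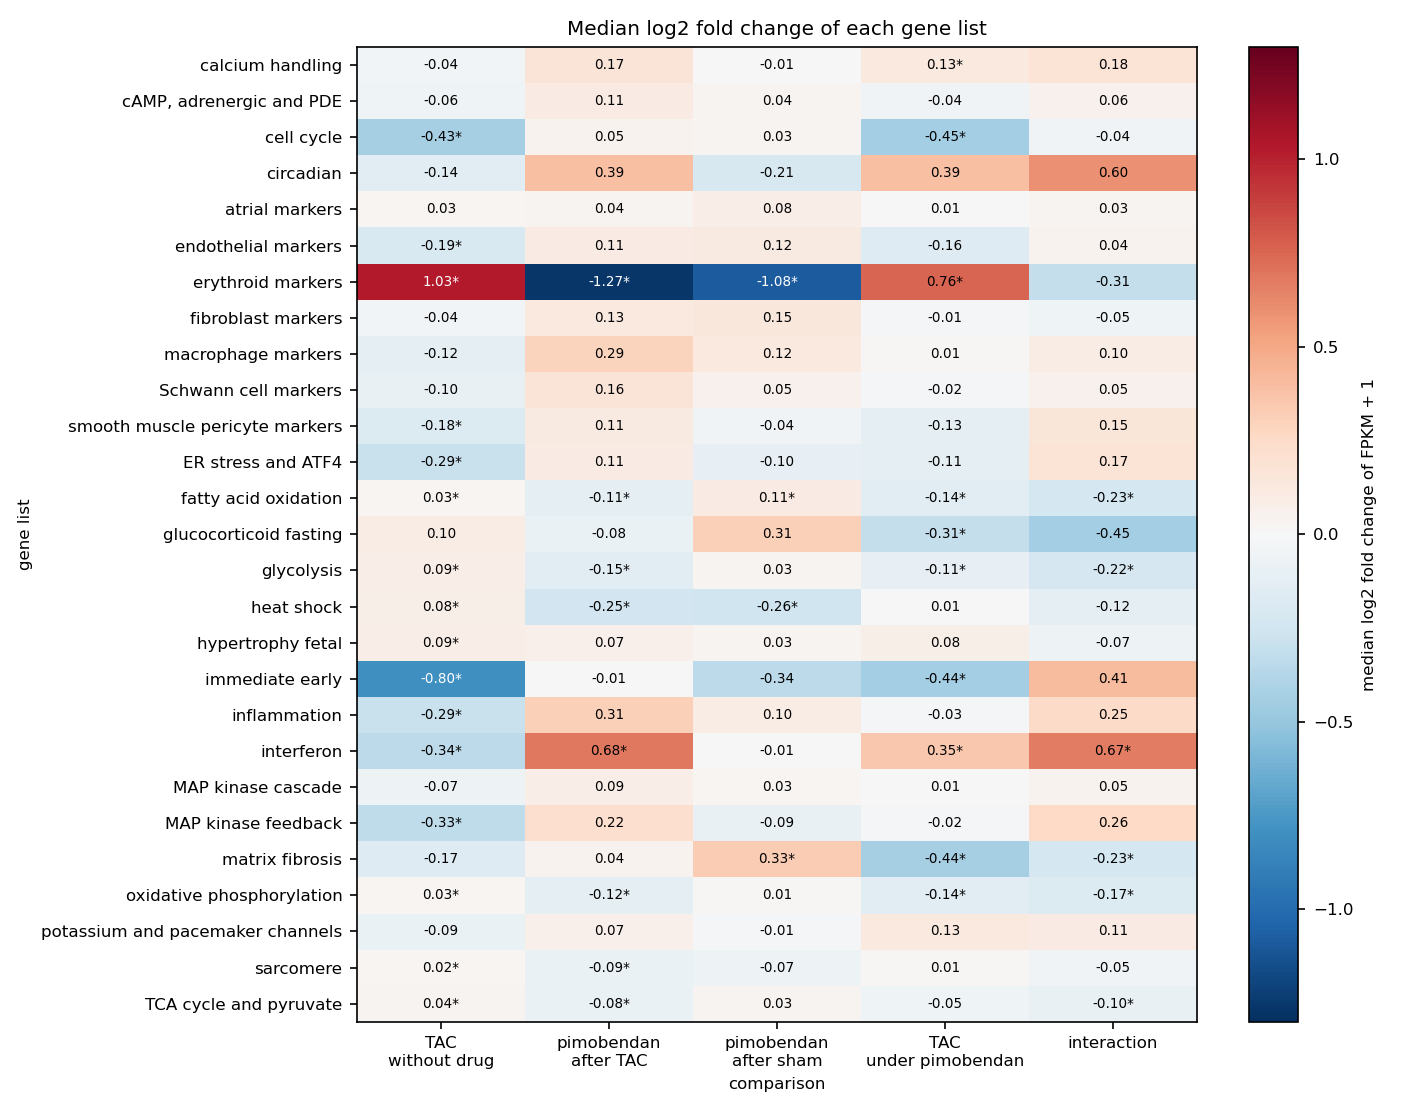
Median log2 fold change of FPKM + 1 over the measured members of each of 27 gene lists (vertical axis) in each comparison (horizontal axis), as number and colour; * marks a camera adjusted p under 0.05 with the preset correlation. None of the marked lists passed with an estimated correlation.

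The interaction asked whether the response to TAC differed between mice with and without pimobendan. No gene passed this test, and interferon-response genes had the largest shift of the lists that camera called. They responded to TAC more positively under the drug (22 of 23 positive, median difference of log2 fold changes 0.67, camera adjusted p = 4.10e-05; adjusted p = 0.925 with an estimated correlation). Of these 7 passed limma adjusted over the list alone and 0 over all genes. Rsad2 differed by 0.87 ± 0.21 (limma adjusted p = 0.0853), Ifit1 by 1.55 ± 0.40 and Lpl by 1.09 ± 0.25 (limma adjusted p = 0.0853). Lists with a negative interaction were oxidative phosphorylation (median -0.17, camera adjusted p = 2.77e-05; adjusted p = 0.925 with an estimated correlation), fatty acid oxidation (-0.23, camera adjusted p = 0.000154; adjusted p = 0.925 with an estimated correlation) and glycolysis (-0.22, camera adjusted p = 0.000232; adjusted p = 0.925 with an estimated correlation). The others were matrix genes (-0.23, camera adjusted p = 0.0128; adjusted p = 0.925 with an estimated correlation) and the TCA cycle (-0.10, camera adjusted p = 0.0264; adjusted p = 0.485 with an estimated correlation). Under quantile normalization camera called none of the oxidative phosphorylation, fatty acid, glycolysis and TCA cycle lists, and the median of the TCA cycle was positive. It did not call the TCA cycle on TPM or matrix genes with the GC and length trend removed. Members with the smallest p were Cpt1b (-0.42 ± 0.11), Pfkfb2 (0.86 ± 0.22), Gpi1 (-0.33), Ndufa1 (0.35), Sdhb (-0.34), Ogdh (-0.33), Sucla2 (0.59), Postn (0.91 ± 0.36) and Eln (-0.93 ± 0.42). Of the hypertrophy markers, Acta1 differed by -1.84 ± 0.85 (95% confidence interval -3.67 to -0.0093; limma adjusted p = 0.244), Nppb by -0.93 ± 0.49, Nppa by 0.71 ± 0.48, Myh7 by 1.28 ± 1.3 and Ankrd1 by 0.53 ± 0.42. Col1a1, Col3a1, Ctgf, Myh6, Atp2a2 and Pde3a differed by -0.36, -0.34, -0.13, 0.037, -0.022 and 0.17.

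For the interaction limma called 0 genes (2312 at an unadjusted p under 0.05; smallest adjusted p = 0.0853; 494 at an adjusted p under 0.1), and rho across genes between GC content and the difference was -0.56. Without TAC+pimobendan replicate 1, 772 genes passed, and with array weights 500. Without TAC+control replicate 1 only Hspa1b passed, and with a pseudocount of 0.1 and no filter 1 (Evi2, chosen after its values were seen). Across genes, the log2 fold changes of TAC without drug and of pimobendan after TAC had r = -0.534. TAC+control enters both with opposite signs, and simulated data with no change in any gene gave a mean r of -0.450 (95% of draws between -0.914 and 0.299). The effect of TAC averaged over both drug arms had 0 genes past limma (1610 at an unadjusted p under 0.05; smallest adjusted p = 0.152), so the planned share of TAC genes with a smaller response under pimobendan had no genes to rest on. Averaged over the arms, leaving out TAC+pimobendan replicate 1 gave 84 genes, TAC+control replicate 1 gave 3 (Hspa1b, Depp1 and Zfp799), Sham+pimobendan replicate 3 gave Cebpd and Nfkbia, Sham+control replicate 3 Nfkbia, Sham+control replicate 1 Cited2 and TAC+control replicate 3 Eif5. Those outside the naming rule were chosen after their values were seen.

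**Figure D4:**
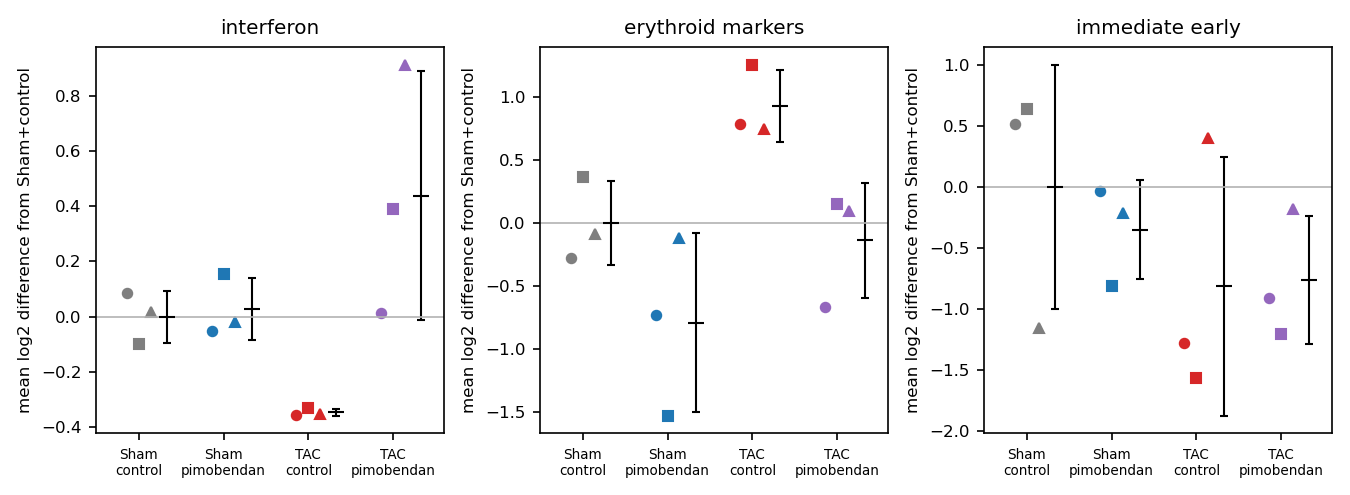
Mean log2 difference from the Sham+control mean of the measured members of the interferon, erythroid and immediate early lists (vertical axis) in each mouse by group (horizontal axis), with circles, squares and triangles for replicates 1, 2 and 3 and bars for mean ± SD (n = 3). The interferon scores of the TAC+control mice lay below those of all other mice.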

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

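The tests of explanations and the counts of other splits were chosen only after the results were seen, while the list tests were planned. Rules of some tests were also changed after their values were seen: the interferon test against sham was made stricter, the test of sample number was moved to the real calls, the test of standard errors was added, the test of a single library for the genes that rose was replaced, and the test against sham for these genes was also asked of corrected values.

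Camera with the preset correlation gave 6 lists whose response to TAC differed between mice with and without pimobendan, that is, a tested difference between groups. The median difference of log2 fold changes was 0.67 for interferon-response genes, -0.17 for oxidative phosphorylation, -0.23 for fatty acid oxidation, -0.22 for glycolysis, -0.23 for matrix genes and -0.10 for the TCA cycle. None held with an estimated correlation (adjusted p = 0.925 with an estimated correlation for the first 5 and 0.485 for the TCA cycle). Of 100 splits drawn, the real one included, 77 gave at least 6 lists, with up to 16 in another split and more than 0 in all 99 others, so chance cannot be excluded for this count. For genes, the real interaction and TAC averaged over both arms had 0, which all 100 splits reach by definition, so this says nothing about chance; the highest other counts were 15 and 41, the latter from a split that exchanged, among others, Sham+control replicate 3 and TAC+control replicate 3.

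For the comparisons of 3 with 3 libraries, 10 splits are too few for a share under 0.05. Pimobendan after TAC had 373 genes and 8 lists in the real split, against at most 0 genes and 15 lists in the others. TAC under pimobendan had 558 genes and 10 lists, against at most 0 genes and 11 lists. Pimobendan after sham had 0 genes and 4 lists, against at most 0 genes and 15 lists. TAC without drug had 0 genes and 16 lists, against at most 53 genes and 13 lists. Of the 10 splits, the real one included, 4, 5, 8 and 1 gave at least as many lists as the real one, in the same order of comparisons.

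With pimobendan after TAC 360 genes were called higher and 13 lower, and the rise went with low GC content and long transcripts. Removing each library's GC and length trend lowered the median log2 fold change of the risen genes from 0.63 (median SE 0.137; quartiles 0.52 and 0.77) to 0.31 (median SE 0.111; quartiles 0.21 and 0.48); 357 of 358 stayed positive and 0 were called, since the fold fell by more than its error did, so the rise and the trend, which TAC+pimobendan libraries shared, cannot be told apart. Median-ratio scaling left a median of 0.57 for these genes and 1 call, so the number of calls depended on scaling. It moved the median of all genes only from 0.095 to 0.027. A rise of this size could therefore not have been removed by it, and the median decides nothing about scaling. A drug response shared by both surgeries is argued against as the whole cause. With pimobendan after sham the same genes had a median of -0.12, or -0.039 (upper quartile 0.067) with the trend removed. This holds for the genes as a set. Without that removal 84 of 360 were positive after sham, and Srsf5 was among them. Against a single TAC+pimobendan library, the 360 top genes of fits without 1 TAC+pimobendan and 1 TAC+control library had a positive median log2 difference of the former from the latter in all 9 pairs, averaging 0.29, 0.46 and 0.47 for TAC+pimobendan replicates 1, 2 and 3; the lowest, 0.11 for TAC+pimobendan replicate 1 and TAC+control replicate 2, was about that of all genes in this pair, and calls shared with the 373 were 359, 0 and 2 without replicates 1, 2 and 3. A drug effect confined to the loaded heart stays open and was not separated from a difference in RNA or library preparation, nor from low values in TAC+control. Above the TAC+control mean, the 360 risen genes had medians of 0.37, 0.17 and 0.16 in Sham+control and 0.17, 0.18 and -0.044 in Sham+pimobendan. In TAC+pimobendan these medians were 0.43, 0.73 and 0.73. The genes were chosen for their difference from TAC+control, so these medians do not decide between the readings.

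Interferon-response genes were higher with pimobendan after TAC in 23 of 23 members. The GC and length trend is not the whole cause, since after its removal the median was 0.58 (quartiles 0.47 and 0.84) with 23 of 23 positive, although 0 were called, as the smallest adjusted p of any gene was 0.120, and the camera adjusted p of 1.32e-13 became adjusted p = 0.499 with an estimated correlation. The difference from TAC+control did not rest on a single TAC+pimobendan library, since the lowest library score was 0.36 above the TAC+control mean. The SD of this score was 0.0125 in TAC+control, 0.094 in Sham+control, 0.11 in Sham+pimobendan and 0.45 in TAC+pimobendan. Every sham library also lay above the TAC+control mean of -0.35, the lowest with a score of -0.10. This therefore does not show that every TAC+pimobendan library had risen. Whether TAC+control was low or TAC+pimobendan high cannot be told apart: TAC+pimobendan exceeded the 6 sham libraries by 0.42 (two-sided exact permutation p = 0.0476) with scores of 0.013, 0.39 and 0.91, the lowest within the sham range, and by 0.19 without replicate 3, and TAC+control differed from them by -0.36 (exact p = 0.0119, the smallest of 84 splits). More macrophages in the tissue may add to it and also stay open, since all 15 macrophage markers were positive with a median of 0.29.

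No gene was called for TAC without drug, although the hypertrophy genes that this surgery is known to induce were measured. In the same fit 373 genes were called between 2 other groups of 3, whatever their cause, so calls were possible with 3 libraries in a group. That count was 0 with only those groups fitted or with the trend removed, and it does not give the power for TAC. Too few samples therefore stays open. Of simulated changes 64 of 67 by a log2 of 1 and 26 of 67 by 0.5 were called. These were genes drawn at random, so smaller changes, and changes of either size in genes with a larger SE, may have been missed. The simulated noise was independent between genes, so the real libraries may allow fewer calls. A candidate explanation is that hypertrophy genes varied more between mice than other genes did: the median SE of the 15 list members was 0.237, 1.89 times that of all genes (0.126), and 11 of 15 lay above it. Whether they moved together below the threshold cannot be told apart from no change, since over 6 TAC and 6 sham libraries the mean log2 difference was 0.12 (95% confidence interval -0.065 to 0.31; exact permutation p = 0.16). A mild constriction in some mice was not tested.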

How the results depend on the processing

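The alternatives on TPM, quantile normalization, GC and length correction, array quality weights, pseudocount 0.1 with the filter kept, and TAC+pimobendan replicates 2 and 3 left out were chosen after seeing the data; the rest were planned. The planned DESeq2 test was not run, since the deposited values are not counts. Counts of called genes are given for pimobendan after TAC (373), TAC under pimobendan (558), TAC without drug (0), pimobendan after sham (0), the interaction (0) and TAC averaged (0). Pimobendan after sham gave 0 genes under every alternative run. Pimobendan after TAC gave 1 gene under median-ratio scaling and 1 with a replicate block, 2 with pseudocount 0.1 and no filter on low values, 1170 on TPM, 1315 with array quality weights, and 22 at an absolute log2 fold change of at least 1. It gave 0 with no filter on low values, with quantile normalization, with GC and length correction, with only the 2 groups compared and with TAC+pimobendan replicates 2 and 3 left out. TAC under pimobendan gave 298 genes with quantile normalization, 51 at an absolute log2 fold change of at least 1 and 1350 with array quality weights. It gave 0 with no filter, with a replicate block, with pseudocount 0.1 and no filter, with GC and length correction, with only the 2 groups compared and with TAC+pimobendan replicates 2 and 3 left out. The interaction gave 500 with array quality weights and 1 with pseudocount 0.1 and no filter; TAC without drug gave 2 with only the 2 groups compared. Leaving out 1 library in turn gave between 0 and 1187 genes for pimobendan after TAC, between 0 and 1222 for TAC under pimobendan, between 0 and 772 for the interaction, between 0 and 84 for TAC averaged and between 0 and 4 for TAC without drug. Where this left a group with 2 libraries, limma pooled the spread over all groups. For lists, the main counts were 16, 8, 4, 10 and 6 (TAC without drug, pimobendan after TAC, pimobendan after sham, TAC under pimobendan, interaction). Each became 0 with an estimated correlation. TAC under pimobendan gave 6 lists with median-ratio scaling, 4 at a mean of at least 1 FPKM, 5 with quantile normalization and 5 with GC and length correction. Quantile normalization gave 5 for pimobendan after TAC and 3 for the interaction. Leaving out 1 library gave between 8 and 16 lists for TAC without drug, between 4 and 10 for pimobendan after sham and between 4 and 8 for TAC under pimobendan. Without TAC+control replicate 1, pimobendan after TAC went from 360 higher and 13 lower to 0 higher and 3 lower, with 0 of the 373 among them. No named gene that passed in either setting changed sign, but some that passed in neither did, among them 3 for TAC without drug under quantile normalization and 3 for pimobendan after TAC on TPM. Of the lists called, oxidative phosphorylation for TAC without drug turned from higher (camera adjusted p = 0.0056) to lower (camera adjusted p = 0.0101) under quantile normalization. That normalization moved the median log2 fold change of all genes from 0.095 to -0.021 for pimobendan after TAC and from 0.066 to -0.038 for the interaction. Calls of named genes were summed over the alternatives, so that a gene counts again for each alternative. In this sum 321 calls of pimobendan after TAC were lost and 34 gained. For TAC under pimobendan 304 were lost and 21 gained, for the interaction 12 were gained, and for TAC without drug 2 were gained. Leaving out libraries and fitting only the 2 groups compared use fewer samples; for the other alternatives the cause was not tested. Replicate numbers did not pair the samples: of 18 pairs with the same number, 4 had r above 0.1 (mean r -0.0855, against 0.0423 for other numbers). Depth is unknown without counts, so what it limits could not be assessed.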

Other observations

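The look at single libraries and at the exchange of libraries was chosen only after the results were seen, while the list tests were planned.

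Camera called the following gene groups in none of the 5 comparisons. Circadian genes (16 measured) had a median log2 fold change of 0.39 with pimobendan after TAC (12 positive, camera adjusted p = 0.813), -0.21 with pimobendan after sham and 0.39 for TAC under pimobendan, where Hlf passed over all genes and as the only member adjusted over the list alone. Genes of cAMP, adrenergic and phosphodiesterase function (24 measured) had medians of -0.056 for TAC without drug and 0.11 with pimobendan after TAC (camera adjusted p = 0.945), where 2 rose over all genes and 3 adjusted over the list alone. Potassium and pacemaker channels (16 measured) had a median of 0.066 with pimobendan after TAC (camera adjusted p = 0.752), with 1 past the test over all genes and 5 adjusted over the list alone. Fibroblast markers (14 measured) had medians of -0.040 for TAC without drug and 0.13 with pimobendan after TAC (camera adjusted p = 0.752). Atrial markers (8 measured) had 0.030 and 0.040 (camera adjusted p = 0.848), and Schwann cell markers (5 measured) had -0.10 and 0.16 (camera adjusted p = 0.974).

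Immediate early and erythroid genes varied between mice of the same group. Immediate early genes, which respond within minutes to handling, ischemia and stimulation, had mean log2 differences from the Sham+control mean of 0.51, 0.64 and -1.16 in Sham+control and -1.28, -1.57 and 0.40 in TAC+control. Exchanging Sham+control replicate 3 and TAC+control replicate 3 gave the split with 53 called genes for TAC without drug, of which 51 were lower in the regrouped TAC set, 13 belonged to the 24 immediate early genes and 3 to the MAP kinase feedback genes, against 0 called in the real split. That split, the highest of the 9 other splits, points to a structure of the samples in immediate early genes, while in 2 other lists these libraries stood with their groups: interferon and erythroid scores were -0.35 and 0.75 in TAC+control replicate 3 and 0.015 and -0.089 in Sham+control replicate 3. In inflammation genes TAC+control replicate 3 stood apart from its group, with scores of -0.49, -0.46 and -0.031 in replicates 1, 2 and 3, and its hypertrophy score was the lowest of the 3 (0.26, 0.13 and -0.0032). Erythroid marker scores were 0.78, 1.26 and 0.75 in TAC+control and -0.73, -1.53 and -0.12 in Sham+pimobendan. Hearts were rinsed before sampling, and blood left in the tissue was not measured separately.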
